A study of Homo sapiens with 13 samples.

How the data were processed

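Messenger RNA was measured in PC3 cells, a human prostate cancer cell line, carrying a short hairpin RNA against TIMP1, a secreted inhibitor of metalloproteinases. The 13 libraries fall into 4 groups by the labels: Vehicle (3 libraries), Docetaxel (4), Adapalene (3) and Combo, the combination of both drugs (3). Docetaxel is a taxane that stabilises microtubules and was given at 1 nM. Adapalene is a synthetic retinoid that activates retinoic acid receptors and was given at 5 µM. Exposure lasted 48 h, and the labels do not restate the doses used in the combination. The design text calls the replicates technical, so every p-value measures only the spread between technical replicates. Cells without the hairpin were not analysed here.

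Per the labels' protocols, polyadenylated RNA was selected with magnetic beads, made into strand-preserving libraries and sequenced as single reads of 120 bp on a NextSeq2000. The submitters' processing notes name FastQC, STAR 2.7.10a, DESeq2 and the genome build GRCh38.p13, without giving the role of each. The counting program, its strand setting and its treatment of reads that map to several places are not given in the sources used here. The deposited table holds raw counts, whole numbers per gene and library as the authors made them, for 67882 Ensembl gene identifiers. Of these identifiers, 61369 had a symbol in the gene name table used here. Coordinates are from GENCODE release 29 on the same genome assembly, and 9516 identifiers of the count table are not in that release.

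Library totals ranged from 11948720 to 16235041 counts, with 21836 to 25058 genes detected per library. The 10 most abundant genes took 3.57 to 4.29% of counts. Mitochondrially encoded genes took 0.722 to 2.82%, and exceeded 2% in Vehicle replicate 3, Docetaxel replicate 4, Adapalene replicate 3 and Combo replicate 3. Replicates of 1 group were compared in 15 pairs. Their log2 values correlated with Pearson's r of 0.979 to 0.993 across genes, and chi-square per degree of freedom was 2.38 to 23.5, so no pair differed as little as sampling noise alone and each library was counted once. Between Vehicle and Combo the libraries with the same replicate number deviated from their group means together (r of 0.257, 0.159 and 0.174 for numbers 1 to 3). Pairs of unlike number between Vehicle and Combo lay lower, at −0.291 to 0.0639. Between other groups libraries with unlike numbers reached higher values (0.341 for Vehicle replicate 3 and Docetaxel replicate 4). These values therefore do not show that the number pairs libraries throughout, and the labels do not say so. In no other comparison did every pair pass 0.1. Between protein-coding genes of the major histocompatibility region (chromosome 6, 28500000 to 33500000) and the rest of the genome the table was uneven. There, 139 of 181 genes held 0 counts in every library (76.8%, against 13.6% elsewhere) and 10 passed the filter on low counts. HLA-C, MICA and TAP1 had at most 2 counts in any library, which limits the lists of antigen presentation (7 of 16 members untested in this region) and of ligands for natural killer cells (2 of 25). The inflammatory list lost TNF (0 counts in all libraries) and the lysosome list NEU1 (at most 2). In the tubulin list TUBB was tested on 7 to 17 counts per library, too few to show the level of that tubulin.

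Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group at its defaults (minimum count 10, minimum total 15), which kept 15734 genes, 14387 of them with a symbol. Libraries were scaled by TMM, and 1 quasi-likelihood model with 4 group means was fitted to all 13 libraries. From it came 5 comparisons between groups and the interaction, which tests whether the effect of adapalene differs with and without docetaxel. A gene is called when its p-value adjusted by the Benjamini-Hochberg method is under 0.05. Levels are CPM values (TMM-scaled, from the cpm function of edgeR), given as mean ± SD. Fold changes are log2 values, with their standard error (SE) where 1 is printed.

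The comparisons, the tests, the rule for naming genes, most of the alternatives and 23 gene lists were fixed before the data were examined. The lists are retinoid response, senescence and arrest, the inflammatory part of the senescence-associated secretory phenotype, ligands and attractants of natural killer cells, interferon response, antigen presentation, mitosis and spindle, DNA replication, tubulin and microtubules, p53 targets, apoptosis regulators, cholesterol synthesis, integrated stress response, hypoxia and glycolysis, epithelial markers, mesenchymal markers, targets of YAP and TGF-beta, TIMP and metalloproteinases, lysosome, replication histones, androgen and luminal markers, fibroblast markers and leukocyte markers. Lists with at least 3 tested members were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 22 lists of a comparison. The same test with a correlation estimated from the data was run beside it, as was fry. A list's median, mean and test differed in sign in 14 of 132 cases, 0 of them past the threshold. Named genes have a symbol and a mean of 1 CPM or more. They are the 8 largest changes in each direction among called genes whose groups do not overlap, up to 4 called members of each list past the threshold, and 15 genes fixed by name. Not all of them are printed, and which to print was decided after their values were seen: several whose call hung on single libraries, or whose reads may belong to a close copy, were left out, so the printed genes look steadier than the full set. A few results for single genes were left out because those genes are withheld for evaluation.

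The procedure was tested on simulated counts with known changes, drawn for each gene independently. Correlation between genes and deviations of whole libraries were not simulated, so false calls owed to them are not counted here. For Docetaxel against Vehicle (15290 genes) it recovered 52.3% of 1.5-fold, 79.7% of 2-fold and 97.0% of 4-fold changes, with 7 false calls. For Combo against Adapalene (15495 genes) it recovered 47.0%, 82.1% and 98.5%, also with 7 false calls, and 1 of 21 unchanged lists passed the preset test. Alternatives were DESeq2 1.42.0, RLE scaling, other filters, a minimum fold change, the replicate number as a block, only the groups compared, and each library left out in turn. Added after seeing the data were fits without libraries over 2% mitochondrial counts, with that share as a covariate, without 2 libraries that lay close to another group, and with only the Combo and Vehicle or only the Combo and Adapalene libraries and the replicate number as a block.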

Results

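RNA was sequenced from PC3 prostate cancer cells with a TIMP1 knockdown after 48 h with vehicle (n = 3), docetaxel (n = 4), adapalene (n = 3) or both drugs (Combo, n = 3). The design asks how docetaxel, a microtubule poison, and adapalene, a retinoid, change gene expression alone and together. Library totals ran from 11948720 to 16235041 counts. Adjusted p-values for genes are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and they measure only the spread between technical replicates. The first principal component held 36.1% of the variance and the second 24.0%.

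TIMP1 (chromosome X, 47582313 to 47586789), the knockdown target, was still detected in all libraries, at 55.0, 65.0 and 61.9 CPM in Vehicle replicates 1 to 3 and at 56.2, 62.0, 71.1 and 64.7 CPM in Docetaxel replicates 1 to 4. Adapalene replicates 1 to 3 stood at 98.4, 105 and 70.4 CPM and Combo replicates 1 to 3 at 98.1, 109 and 112 CPM. TIMP1 was higher with adapalene than with vehicle (log2 fold change 0.59, SE 0.13, edgeR adjusted p = 0.00532) and with Combo (0.81, SE 0.13, edgeR adjusted p = 0.000418). With docetaxel alone it differed by less than the spread between replicates (0.07, SE 0.12, edgeR adjusted p = 0.727). No library without the hairpin was analysed here, so the size of the knockdown was not measured.

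**Figure D1:**
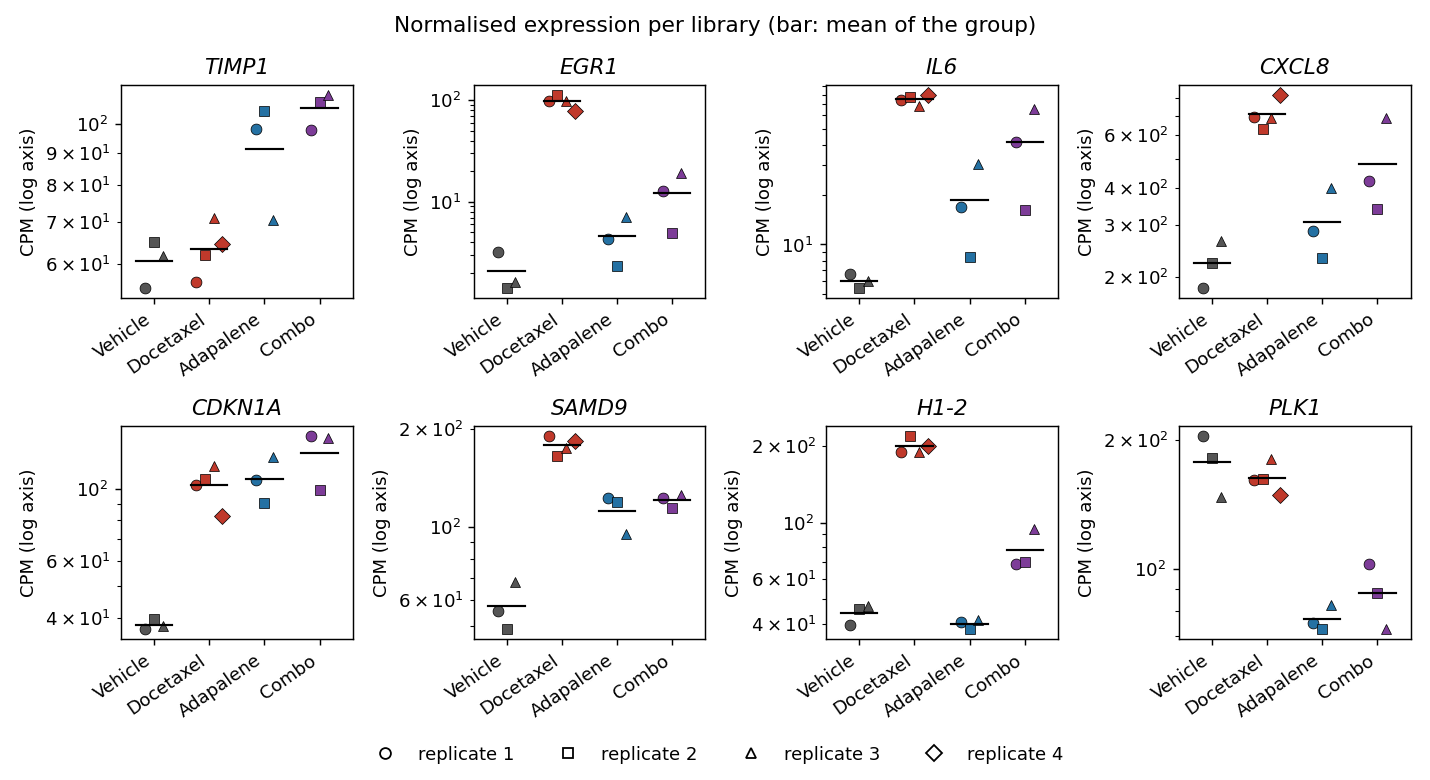
Expression of 8 genes in each library, in CPM on a log axis, by group; symbols mark replicate numbers and bars the mean of the group. EGR1 averaged 97.6 CPM in Docetaxel and 12.3 CPM in Combo, H1-2 averaged 200 and 77.8 CPM, and PLK1 averaged 178 CPM in Vehicle and 76.7 CPM in Adapalene.

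Docetaxel alone raised inflammatory genes. IL6 (chromosome 7, 22725884 to 22732002), a cytokine, averaged 6.05 ± 0.6 CPM (SD, n = 3) in Vehicle and 74.8 ± 5.28 CPM (SD, n = 4) in Docetaxel, a log2 fold change of 3.63 (SE 0.43, edgeR adjusted p = 3.57e-05). The neutrophil attractant CXCL8 rose from 224 ± 40.3 to 708 ± 82.0 CPM (log2 1.66), and IL1A, CXCL2 and CSF2, all secreted signals, rose by 3.20, 2.79 and 2.43 on the log2 scale. Of 25 tested members of the inflammatory secretory list, 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 1.66. That list passed camera (adjusted p = 7.41e-34) and held with an estimated correlation (adjusted p = 0.00881). The largest rises included the immediate-early transcription factor EGR1 (chromosome 5, 138465490 to 138469315), 47.4-fold from 2.07 ± 0.970 to 97.6 ± 14.1 CPM (edgeR adjusted p = 7.06e-07), and the cytokine IL24, 18.7-fold to 95.2 ± 21.7 CPM.

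Replication histone transcripts rose in the same libraries. H1-2, a linker histone (chromosome 6, 26055787 to 26056428), went from 44.1 ± 4.01 to 200 ± 14.2 CPM (log2 2.18, SE 0.11, edgeR adjusted p = 2.97e-08), and the H2B gene H2BC12 from 40.6 ± 2.08 to 121 ± 13 CPM (log2 1.57). All 10 tested histones of the list rose (10 adjusted over the list alone, median 2.17), past camera (adjusted p = 1.51e-37) and with an estimated correlation (adjusted p = 0.00881). Histone genes are near-identical copies, and how shared reads were counted is not given in the sources used here, so the value of a single histone gene is uncertain. Most of their transcripts carry no poly(A) tail, and the libraries were made from polyadenylated RNA.

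Interferon-stimulated genes rose as well: 30 of 33 tested members, with 0 falling (32 and 0 adjusted over the list alone, median 1.05, camera adjusted p = 1.99e-27, adjusted p = 0.135 with an estimated correlation). SAMD9, an antiviral factor, went from 57.6 ± 9.83 to 178 ± 10.8 CPM (log2 1.63), the transcription factor IRF1 rose by 1.55, and OASL and IFIT2 rose by 1.14 and 1.16. In the list of ligands and attractants of natural killer cells 9 of 19 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.40, camera adjusted p = 0.000481, adjusted p = 0.208 with an estimated correlation). These included ICAM1, an adhesion molecule, by 0.86, and ULBP2, a ligand of the activating receptor NKG2D, by 0.64, although ULBP2 has close relatives and its single value is uncertain. The stress list had 10 of 21 members up and 3 down (10 and 5 adjusted over the list alone, camera adjusted p = 0.00132, adjusted p = 0.286 with an estimated correlation). The transcription factor genes ATF3 and DDIT3 rose by 2.81 and 1.23. Among apoptosis regulators 9 of 21 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00909, adjusted p = 0.135 with an estimated correlation). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose by 1.09. Targets of YAP and TGF-beta had 10 of 17 up and 1 down (10 and 1 adjusted over the list alone, camera adjusted p = 0.000481, adjusted p = 0.286 with an estimated correlation). The matricellular gene CCN1 rose by 0.84 and the kinase gene LATS2 by 0.72.

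Genes of DNA replication fell with docetaxel, 23 of 30 with 0 rising (26 and 0 adjusted over the list alone, median −0.42, camera adjusted p = 2.13e-15, adjusted p = 0.198 with an estimated correlation). MCM6, part of the replicative helicase, went from 202 ± 15.4 to 124 ± 7.99 CPM (log2 −0.70), and LMNB1, a nuclear lamin, from 162 ± 18.7 to 95.9 ± 1.98 CPM (log2 −0.76). Of 29 mitotic genes 17 fell and 0 rose (19 and 0 adjusted over the list alone, median −0.27, camera adjusted p = 5.57e-07, adjusted p = 0.265 with an estimated correlation). The topoisomerase gene TOP2A stood at −0.67 and the kinetochore gene CENPF at −0.47. In cholesterol synthesis 14 of 23 fell and 0 rose (16 and 0 adjusted over the list alone, median −0.31, camera adjusted p = 3.28e-06, adjusted p = 0.208 with an estimated correlation). The cyclin-dependent kinase inhibitor CDKN1A (chromosome 6, 36676460 to 36687339) rose from 38.1 ± 1.5 to 103 ± 14.7 CPM (log2 1.43, SE 0.15, edgeR adjusted p = 1.18e-05), while the proliferation marker MKI67 stood at 593 ± 80.1 and 492 ± 21.8 CPM (edgeR adjusted p = 0.0857). In PC3 cells, which carry no functional p53, the p53 target list did not pass (4 of 18 up, 1 down, camera adjusted p = 0.163).

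In all, docetaxel changed 4082 of 15734 tested genes, 2073 up and 2009 down, by the edgeR test. Of these, 854 rises and 60 falls were at least 2-fold (log2 1). The largest fall among the named genes printed here was that of the cartilage collagen COL2A1, from 17.8 ± 8.37 to 3.40 ± 1.02 CPM (log2 −2.37). Of 22 lists tested, 12 passed camera. The inflammatory and the histone list, 2 of them, held with an estimated correlation. The lysosome list (4 of 17 down, camera adjusted p = 0.0374, adjusted p = 0.265 with an estimated correlation) lost its call without Vehicle replicate 1, Vehicle replicate 2, Docetaxel replicate 3 or Docetaxel replicate 4 (camera adjusted p = 0.0746, 0.0544, 0.0711 and 0.0803), and with the replicate number as a block (0.0903). The mesenchymal list (6 of 19 up, 2 down, camera adjusted p = 0.0301, adjusted p = 0.286 with an estimated correlation) lost it without Vehicle replicate 2 or 3 (0.0753 and 0.0704). Gene calls numbered 2347 without Vehicle replicate 2 and 2660 without Docetaxel replicate 2.

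Adapalene alone lowered mitotic genes. PLK1, a kinase of mitotic entry (chromosome 16, 23677656 to 23690367), went from 178 ± 28.8 CPM (SD, n = 3) in Vehicle to 76.7 ± 5.22 CPM (SD, n = 3) in Adapalene (log2 −1.21, SE 0.13, edgeR adjusted p = 4.81e-05). The mitotic kinesins KIF20A and KIF14 fell by 1.06 and 0.98, the spindle protein gene HMMR fell by 0.97 and cyclin B1 (CCNB1) fell by 0.96 on the log2 scale. Of 29 tested mitotic genes 26 fell and 0 rose (27 and 0 adjusted over the list alone, median −0.73), past camera (adjusted p = 1.97e-46) and with an estimated correlation (adjusted p = 0.0306). MKI67 fell from 593 ± 80.1 to 350 ± 48.3 CPM (log2 −0.76). STAG1, a cohesin subunit gene, went from 65.2 ± 7.45 to 29.4 ± 4.40 CPM (log2 −1.15). In DNA replication 13 of 30 fell and 2 rose (13 and 3 adjusted over the list alone, median −0.20, camera adjusted p = 2.32e-05, adjusted p = 0.371 with an estimated correlation). MCM6 and LMNB1 fell by 0.77 and 0.76.

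CDKN1A rose to 108 ± 17.6 CPM with adapalene (log2 1.5, SE 0.16, edgeR adjusted p = 4.66e-05). In the stress list 13 of 21 rose and 0 fell (16 and 1 adjusted over the list alone, median 0.55, camera adjusted p = 1.52e-07, adjusted p = 0.187 with an estimated correlation). CHAC1, which degrades glutathione, rose by 1.48, the mTORC1 inhibitor gene DDIT4 by 0.95 and the serine synthesis gene PSAT1 by 0.56. Interferon-stimulated genes had 10 of 33 up and 0 down (12 and 0 adjusted over the list alone, median 0.58, camera adjusted p = 4.16e-08, adjusted p = 0.336 with an estimated correlation). IFIT2 rose by 1.01, SAMD9 by 0.96 and OASL by 0.88. The inflammatory list had 6 of 25 up and 0 down (12 and 0 adjusted over the list alone, median 0.45, camera adjusted p = 0.000162, adjusted p = 0.327 with an estimated correlation). Among them the chemokine gene CXCL6 went from 29 ± 2.03 to 60.5 ± 4.38 CPM and IL1B from 14.7 ± 2.29 to 26.3 ± 2.04 CPM. Natural killer ligands had 6 of 19 up and 0 down (6 and 0 adjusted over the list alone, camera adjusted p = 0.00173, adjusted p = 0.273 with an estimated correlation). ULBP2 rose from 10.0 ± 0.350 to 17.0 ± 1.27 CPM. Antigen presentation had 4 of 9 up and 0 down (6 and 0 adjusted over the list alone, camera adjusted p = 0.0098, adjusted p = 0.187 with an estimated correlation).

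IL6 stood at 16.7, 8.39 and 30.7 CPM in Adapalene replicates 1 to 3. Its call (log2 1.62, edgeR adjusted p = 0.0247) was lost without Vehicle replicate 1, 2 or 3 or Adapalene replicate 1 or 3, with edgeR adjusted p up to 0.114. CXCL8 was not called (log2 0.45, edgeR adjusted p = 0.178).

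Large rises from a low level with adapalene were those of BGN, a matrix proteoglycan gene, from 1.32 ± 0.0269 to 7.12 ± 0.632 CPM (log2 2.43), the mucin gene MUC13 from 0.880 ± 0.139 to 5.06 ± 0.164 CPM (log2 2.51) and the potassium channel gene KCNK9 from 0.571 ± 0.121 to 3.12 ± 0.653 CPM (log2 2.45). DHRS2, a dehydrogenase gene, fell from 16.6 ± 2.49 to 6.42 ± 2.67 CPM (log2 −1.37). The fibrillar collagen genes COL5A1 and COL1A1 rose by 0.93 and 0.73, and EPCAM, an epithelial adhesion gene, fell by 0.50. The p53 target list passed, with 5 of 18 up and 1 down (6 and 1 adjusted over the list alone, camera adjusted p = 0.0252, adjusted p = 0.179 with an estimated correlation). PC3 cells carry no functional p53, and CDKN1A, among the genes that rose, is in the senescence and arrest list too. A call of the p53 list in any group therefore does not show p53 activity. Among apoptosis regulators BMF, a pro-apoptotic gene, rose by 1.71 and BIRC5, the survivin gene, fell by 0.63 (list: 5 of 21 up, 1 down; 6 and 1 adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.187 with an estimated correlation). Without Vehicle replicate 3 that list lost its call (camera adjusted p = 0.0758), as did the senescence and arrest list (0.0507, against 0.0118 with all libraries, adjusted p = 0.162 with an estimated correlation). The epithelial list (5 of 19 down, 1 up, camera adjusted p = 0.00593, adjusted p = 0.407 with an estimated correlation) lost it without Adapalene replicate 3 (0.151). The mesenchymal list (7 of 19 up, 1 down, camera adjusted p = 0.0263, adjusted p = 0.336 with an estimated correlation) lost it without Vehicle replicate 2, Vehicle replicate 3 or Adapalene replicate 3 (0.0714, 0.0823 and 0.134).

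Retinoid targets as a list did not pass with adapalene: of 24 tested members 1 rose and 1 fell (1 and 0 adjusted over the list alone, median 0.07, camera adjusted p = 0.954, fry adjusted p = 0.524). With docetaxel 4 rose and 1 fell (camera adjusted p = 0.273, fry adjusted p = 0.000558). The member that fell with adapalene was RARA, a retinoic acid receptor gene (log2 −0.27, edgeR adjusted p = 0.0383), a call lost without Vehicle replicate 1 or 2 or without any 1 of the Adapalene libraries, with edgeR adjusted p up to 0.167, and with the replicate number as a block (0.0582). RARB, a receptor gene commonly induced by retinoids, stood at 2.84 ± 0.491 CPM in Vehicle and 1.46 ± 0.366 CPM in Adapalene (edgeR adjusted p = 0.0578, DESeq2 adjusted p = 0.0406). RARG and DHRS3, a retinaldehyde reductase gene, were not called (log2 −0.08 and 0.10). CYP26A1, which encodes an enzyme that clears retinoic acid, had at most 3 counts in any library and was not tested.

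Adapalene changed 2896 genes by the edgeR test, 1455 up and 1441 down, of which 437 and 40 by at least 2-fold. Of 22 lists 12 passed camera, and 1, mitosis, held with an estimated correlation. Gene calls numbered 1494 without Vehicle replicate 1, 1609 without Vehicle replicate 2 and 1616 without Adapalene replicate 1.

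Docetaxel and adapalene called 507 genes up in common and 466 down in common, against 191.7 and 184 for independent lists of those sizes, and 111 genes in opposite directions. Both comparisons use the same Vehicle libraries. Simulated unchanged groups against those libraries gave at most 0 shared calls in 20 simulations, and a correlation of 0.52 across genes where 0.52 was observed. Each simulated comparison had 0 or 1 calls, so shared calls could hardly arise and their absence does not bear on the overlap. The covariance of the fold changes was 0.158, against 0.0260 in the simulations. The 3 Vehicle libraries cannot be split into 2 sets of 2, so the part of the excess in shared calls owed to the shared libraries was not measured.

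With both drugs together mitotic genes were low, as with adapalene alone. Of 29 members 27 fell and 0 rose against Vehicle (28 and 0 adjusted over the list alone, median −0.75, camera adjusted p = 1.81e-41, adjusted p = 0.0386 with an estimated correlation). KIF14 fell by 1.03 and PLK1 averaged 87.8 ± 15.2 CPM (SD, n = 3). CDKN1A stood at 130 ± 26.4 CPM (log2 1.77 against Vehicle, SE 0.16, edgeR adjusted p = 8.79e-06). The stress list had 16 of 21 up and 0 down (16 and 1 adjusted over the list alone, median 0.54, camera adjusted p = 1.3e-10, adjusted p = 0.0825 with an estimated correlation). CHAC1 rose by 1.88 and DDIT4 by 1.35. Inflammatory genes had 19 of 25 up and 0 down (19 and 0 adjusted over the list alone, median 1.2, camera adjusted p = 3.48e-17, adjusted p = 0.0825 with an estimated correlation). CXCL6 rose by 1.47, CCL20, a chemokine gene, by 3.46 from 0.438 ± 0.129 to 4.86 ± 1.69 CPM, and IL6 by 2.77. IL6 varied between Combo libraries, at 41.6, 16.2 and 66.0 CPM in replicates 1 to 3.

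Interferon-stimulated genes had 12 of 33 up and 0 down in Combo against Vehicle (12 and 0 adjusted over the list alone, median 0.61, camera adjusted p = 4.73e-09, adjusted p = 0.242 with an estimated correlation). Replication histones had 8 of 10 up (8 adjusted over the list alone, median 0.72, camera adjusted p = 1.56e-05, adjusted p = 0.199 with an estimated correlation). Natural killer ligands had 11 of 19 up and 0 down (12 and 0 adjusted over the list alone, camera adjusted p = 2.1e-05, adjusted p = 0.111 with an estimated correlation). ICAM1 stood at 159 ± 33.0 CPM, log2 1.13 above Vehicle. DNA replication had 15 of 30 down and 0 up (16 and 1 adjusted over the list alone, camera adjusted p = 1.97e-08, adjusted p = 0.214 with an estimated correlation). HMGB2, a chromatin protein gene, fell by 0.64. Apoptosis regulators had 9 of 21 up and 1 down (camera adjusted p = 0.00845, adjusted p = 0.0825 with an estimated correlation). p53 targets had 6 of 18 up and 2 down (0.0129, adjusted p = 0.0825 with an estimated correlation), and antigen presentation had 5 of 9 up (0.016, adjusted p = 0.161 with an estimated correlation). Mesenchymal markers had 8 of 19 up and 1 down (0.00908, adjusted p = 0.211 with an estimated correlation). Adjusted over the list alone these 4 had 9 and 1, 6 and 2, 5 and 0, and 11 and 2. GDF15, a stress-induced cytokine gene in the p53 and senescence lists, rose from 95.2 ± 19.1 to 259 ± 71.0 CPM, and NGFR, a neurotrophin receptor gene, from 0.598 ± 0.174 to 4.79 ± 2.38 CPM.

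Metalloproteinases and their inhibitors had 6 of 15 up and 1 down in Combo (8 and 2 adjusted over the list alone, camera adjusted p = 0.0202, adjusted p = 0.0825 with an estimated correlation). MMP14, a membrane-bound metalloproteinase gene, rose by 0.61 beside TIMP1 itself. The list lost its call without Combo replicate 2 (camera adjusted p = 0.0571). Tubulins and microtubule-binding genes had 5 of 18 up and 2 down (5 and 2 adjusted over the list alone; 0.039, adjusted p = 0.341 with an estimated correlation), a call lost without Vehicle replicate 3 or Combo replicate 1 (0.208 and 0.0778). TUBB4A rose by 0.74 and TUBA1A by 1.02, although tubulin genes are close copies and their single values are uncertain. Both were also high with adapalene alone, TUBB4A at 118, 114 and 111 CPM and TUBA1A at 90, 93 and 76 CPM in replicates 1 to 3. Vehicle libraries ranged from 59 to 76 CPM for TUBB4A and from 41 to 51 CPM for TUBA1A. With docetaxel alone the ranges were 50 to 57 and 53 to 65 CPM. TUBB3, a tubulin linked to taxane resistance, was not called between Vehicle and Combo (1.62 ± 0.221 and 2.53 ± 0.781 CPM). Hypoxia and glycolysis genes had 6 of 17 up and 0 down (6 and 0 adjusted over the list alone; 0.0347, adjusted p = 0.205 with an estimated correlation). The peptide hormone gene ADM rose by 1.82, and the list call was lost without Vehicle replicate 3, Combo replicate 1 or Combo replicate 2 (0.0503, 0.0763 and 0.0642). Senescence and arrest genes had 5 of 15 up and 1 down (5 and 1 adjusted over the list alone; 0.016, adjusted p = 0.0825 with an estimated correlation), a call lost without Vehicle replicate 3 (0.0503).

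The combination changed 4058 genes against Vehicle by the edgeR test, 2117 up and 1941 down, 766 and 47 of them by at least 2-fold. Of 22 lists 15 passed camera and 1, mitosis, held with an estimated correlation. Gene calls numbered 2668 without Vehicle replicate 1 and 2486 without Combo replicate 3. Markers of other cell types did not pass camera against Vehicle in any group: fibroblast markers had camera adjusted p = 0.917, 0.115 and 0.179 in Docetaxel, Adapalene and Combo, on 6 tested members, of which 1, 2 and 1 rose and 2, 0 and 0 fell (1, 2 and 3 up and 2, 0 and 0 down adjusted over the list alone). By fry the list passed in Adapalene and Combo (adjusted p = 0.00774 and 0.00548) and not in Docetaxel (0.685). Leukocyte markers had 2 of 16 members above the filter on low counts, too few to test, with median log2 fold changes of 0.60, 0.82 and 0.99, and 1 of the 2 was called up in Combo.

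**Figure D2:**
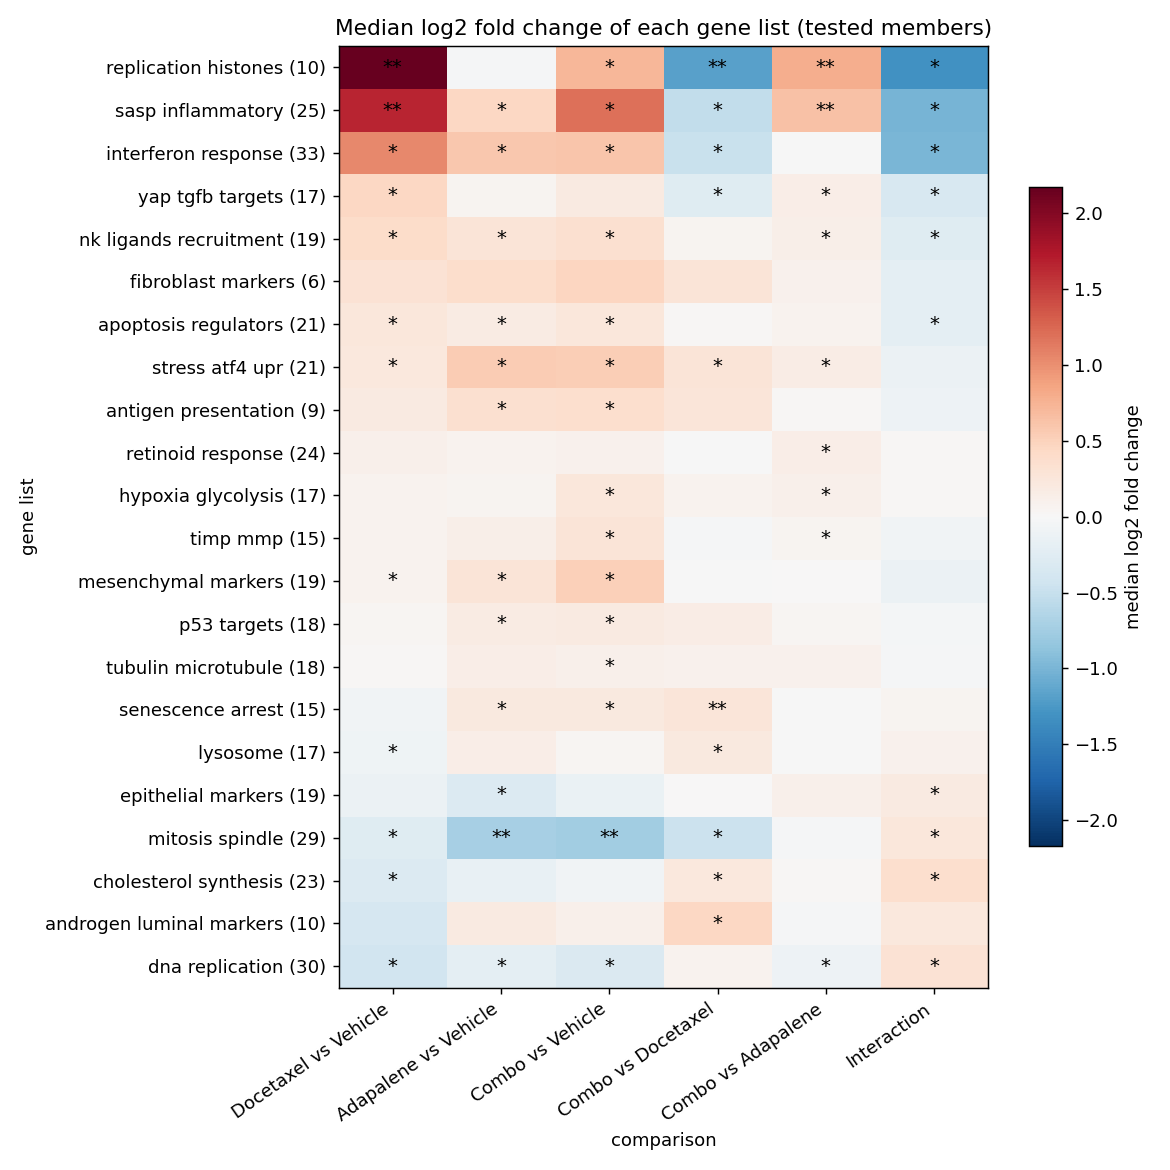
Median log2 fold change of the tested members (number in brackets) of each gene list, by comparison; red is higher and blue lower in the first-named group, 1 asterisk marks lists past camera and 2 asterisks those that also held with an estimated correlation. Replication histones had medians of 2.17 in Docetaxel against Vehicle and −1.18 in Combo against Docetaxel, and mitotic genes −0.73 in Adapalene against Vehicle.

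Adding adapalene to docetaxel lowered histone, mitotic and part of the inflammatory transcripts. H1-2 stood at 200 ± 14.2 CPM (SD, n = 4) in Docetaxel and 77.8 ± 14.6 CPM (SD, n = 3) in Combo (log2 −1.36, SE 0.11, edgeR adjusted p = 2.33e-06), and all 10 tested histones of the list fell (10 adjusted over the list alone, median −1.18, camera adjusted p = 2.51e-20, adjusted p = 0.0307 with an estimated correlation). Mitotic genes fell in 24 of 29 cases with 0 rising (26 and 0 adjusted over the list alone, median −0.46, camera adjusted p = 4.76e-20, adjusted p = 0.11 with an estimated correlation), the kinetochore motor gene CENPE and CCNB1 among them (log2 −0.90 and −0.74). EGR1 fell from 97.6 ± 14.1 to 12.3 ± 7.13 CPM (log2 −2.99), and IL24 from 95.2 ± 21.7 to 19.5 ± 9.84 CPM. DHRS2, raised by docetaxel alone to 76.9 ± 5.02 CPM, was at 9.43 ± 1.88 CPM in Combo (log2 −3.03, SE 0.19, edgeR adjusted p = 2.91e-07).

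Of 25 inflammatory genes 8 fell and 1 rose between Docetaxel and Combo (15 and 2 adjusted over the list alone, median −0.54, camera adjusted p = 0.000228, adjusted p = 0.396 with an estimated correlation). The growth factor gene AREG fell by 0.83 and IL1A fell by 1.05, CXCL6 rose by 0.50, and IL6 and CXCL8 were not called (log2 −0.86 and −0.55; edgeR adjusted p = 0.0861 and 0.0687). Interferon-stimulated genes had 13 of 33 down and 0 up (15 and 0 adjusted over the list alone, median −0.48, camera adjusted p = 8.4e-07, adjusted p = 0.422 with an estimated correlation). IFIT1 stood at −1.09 and SAMD9 at −0.56. Senescence and arrest genes rose in 8 of 15 cases with 0 falling (9 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 0.000398) and held with an estimated correlation (adjusted p = 0.0307). The members with the smallest p were the growth factor gene TGFB1 (log2 0.59) and the insulin-like growth factor binding protein genes IGFBP5 (0.65) and IGFBP6 (0.49), while CDKN1A was not called (0.34, edgeR adjusted p = 0.0855). IGFBP5 still lay below Vehicle, at 46.3, 50.0 and 42.8 CPM in Combo replicates 1 to 3 against 74.3, 70.2 and 65.7 CPM. TGFB1 and IGFBP6 were higher in each Combo library than in any Vehicle library. CDKN1A, IL6 and CXCL8 were called in some fits without 1 library, CDKN1A without Combo replicate 2 (0.50, edgeR adjusted p = 0.0159) and IL6 and CXCL8 without Combo replicate 3 (edgeR adjusted p = 0.0174 and 0.00637). With the replicate number as a block IL6 and CXCL8 were called too (0.0352 and 0.0233).

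Serine synthesis genes of the stress list were higher in Combo than in Docetaxel, PHGDH by 0.91 and PSAT1 by 0.92 (list: 10 of 21 up, 1 down; 10 and 1 adjusted over the list alone, camera adjusted p = 0.000867, adjusted p = 0.396 with an estimated correlation), and without Combo replicate 3 the list lost its call (camera adjusted p = 0.0588). Cholesterol synthesis had 9 of 23 up and 0 down (13 and 0 adjusted over the list alone, camera adjusted p = 0.000866, adjusted p = 0.396 with an estimated correlation). Lysosomal genes had 10 of 17 up and 1 down (10 and 2 adjusted over the list alone, camera adjusted p = 0.00518, adjusted p = 0.227 with an estimated correlation). The protease gene CTSD rose by 0.31. Androgen and luminal markers had 4 of 10 up and 0 down (8 and 0 adjusted over the list alone, camera adjusted p = 0.00676, adjusted p = 0.227 with an estimated correlation). YAP and TGF-beta targets had 6 of 17 down and 1 up (7 and 1 adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.539 with an estimated correlation). The matricellular genes THBS1 and CCN2 were among those that fell (log2 −0.93 and −0.89). The list call was lost without Combo replicate 2 (camera adjusted p = 0.124). BGN rose by 2.49. The edgeR test called 3783 genes in this comparison, 2014 up and 1769 down, 297 and 264 of them by at least 2-fold, and 2292 without Combo replicate 2. Of 22 lists 10 passed camera, and 2 held with an estimated correlation, the histone and the senescence list.

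Adding docetaxel to adapalene raised histone transcripts, and the count of single genes called depended on the processing. With all libraries the edgeR test called 6 genes, all up: the histone genes H1-2 (log2 0.96, SE 0.11, edgeR adjusted p = 0.00539), H2BC4 (0.96), H2BC12 (0.76) and H1-10 (0.56), the transcription factor gene JUNB (0.67) and the kinase gene PIM3 (0.64). H1-2 stood at 40.6, 38.0 and 41.1 CPM in Adapalene replicates 1 to 3 and at 68.7, 70.1 and 94.6 CPM in Combo replicates 1 to 3. As a list, replication histones had 3 of 10 up (8 adjusted over the list alone, median 0.79, camera adjusted p = 2.25e-32, adjusted p = 0.00828 with an estimated correlation). The inflammatory list, with 0 of 25 members called over all genes and 16 adjusted over the list alone, passed too (median 0.64, camera adjusted p = 1.06e-34, adjusted p = 0.00828 with an estimated correlation).

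At an unadjusted p under 0.05 there were 793 genes between Combo and Adapalene, and DESeq2 called 39. The edgeR test called 128 without a filter on low counts and 379 without Adapalene replicate 3 and Combo replicate 2, a fit chosen after the data were seen. With the replicate number as a block it called 2, H1-2 and H2BC12 (edgeR adjusted p = 0.0171 and 0.0203), and with only these 2 groups 0. With that block in only these 2 groups, also chosen after the data were seen, it called 75, although the deviations of Adapalene and Combo replicate 1 hardly correlated (r of 0.0202), so the data do not show the number to pair these groups throughout. Without Adapalene replicate 1, 0 genes were called, and H1-2 had an edgeR adjusted p of 0.0583. H2BC12 was lost without Adapalene replicate 1 or 2 (up to 0.0852), H2BC4, JUNB and PIM3 without Adapalene replicate 1, Adapalene replicate 2 or Combo replicate 3, and H1-10 without these or Adapalene replicate 3 (up to 0.233 each). There was 1 call without Adapalene replicate 2, 19 without Adapalene replicate 3, 33 without Combo replicate 2 and 3 without Combo replicate 3. The other lists past camera in this comparison lost their calls without 1 library and with an estimated correlation. These were the stress list (adjusted p = 0.365 with an estimated correlation, camera adjusted p = 0.223 without Combo replicate 3), DNA replication (0.558; 0.222 without Combo replicate 3) and natural killer ligands (0.365; 0.0688 without Adapalene replicate 2 and 0.156 without Combo replicate 3). The same held for retinoid response (0.06; 0.146 without Adapalene replicate 3), hypoxia (0.0916; 0.211 without Adapalene replicate 3), metalloproteinases (0.0693; 0.139 without Combo replicate 2) and YAP and TGF-beta targets. That last list had 0.656 with an estimated correlation, and 0.0996, 0.751, 0.446 and 0.479 by camera without Adapalene replicate 1, Adapalene replicate 2, Combo replicate 1 and Combo replicate 3.

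The effect of each drug was compared with and without the other, in comparisons that share no library. Across 15734 genes, which are not independent replicates, the effect of adapalene with and without docetaxel correlated with Pearson's r of 0.36 (Spearman's rho 0.42), and the effect of docetaxel with and without adapalene with 0.44 (rho 0.39). Genes raised by adapalene alone had a median log2 change of 0.66 there and 0.38 when adapalene was added to docetaxel, and 83.6% kept their sign. Genes raised by docetaxel alone had a median of 0.81 there and 0.15 when docetaxel was added to adapalene, and 81.0% kept their sign. In each case the first median is raised by the choice of genes. The first r was 0.25 without Adapalene replicate 2, 0.44 without Adapalene replicate 3 and 0.20 without Combo replicate 3. The second was 0.21 without Adapalene replicate 2 and 0.13 without Combo replicate 3.

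The interaction test asked whether the combination departs from the sum of both effects on the log2 scale. EGR1 fell short of that sum by an interaction of −4.14 (SE 0.60, edgeR adjusted p = 0.00399), IL24 by −3.35, the interferon-stimulated genes RSAD2, SAMD9, IFIT2 and OASL by −1.82, −1.52, −0.99 and −0.97, and CDKN1A by −1.16 (edgeR adjusted p = 0.0124). CDKN1A averaged 103, 108 and 130 CPM in Docetaxel, Adapalene and Combo, against 38.1 CPM in Vehicle. Histones H1-2, H2BC4 and H2BC12 had interactions of −1.22, −1.21 and −0.81. In the other direction stood NUP210, a nuclear pore gene (0.90), and IGFBP5 (0.79). The edgeR test called 227 genes, 194 negative and 33 positive, and all 194 were up and all 33 down with docetaxel alone. Choosing genes by a negative interaction favours those raised by docetaxel alone and those raised by adapalene alone.

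Of 22 lists 10 passed camera for the interaction and 0 held with an estimated correlation. Interferon-stimulated genes had 12 of 33 members negative (28 adjusted over the list alone, median −0.99, camera adjusted p = 1.22e-31, adjusted p = 0.127 with an estimated correlation). Inflammatory genes had 6 of 25 (17 adjusted over the list alone, median −1, camera adjusted p = 1.16e-17, adjusted p = 0.0691 with an estimated correlation). Histones had 7 of 10 (10 adjusted over the list alone, median −1.31, camera adjusted p = 9.41e-20, adjusted p = 0.0691 with an estimated correlation). DNA replication had 3 of 30 members positive (15 adjusted over the list alone, median 0.31, camera adjusted p = 3.72e-12, adjusted p = 0.255 with an estimated correlation). Cholesterol synthesis had 2 of 23 (10 adjusted over the list alone, median 0.36, camera adjusted p = 2.84e-09, adjusted p = 0.168 with an estimated correlation). The other 5 lists past camera were mitosis (median 0.24; 0 of 29 called, camera adjusted p = 1.47e-06, adjusted p = 0.407 with an estimated correlation), YAP and TGF-beta targets (−0.36; 0 of 17; 0.00409, adjusted p = 0.443 with an estimated correlation), natural killer ligands (−0.26; 0 of 19; 0.0152, adjusted p = 0.419 with an estimated correlation), epithelial markers (0.20; 0 of 19; 0.0186, adjusted p = 0.449 with an estimated correlation) and apoptosis regulators (−0.20; 1 of 21 negative; 0.0219, adjusted p = 0.168 with an estimated correlation). Adjusted over the list alone 0, 1, 2, 0 and 2 of their members were called. Without 1 library 4 of these lost their calls: YAP and TGF-beta targets without Vehicle replicate 3 or Adapalene replicate 3 (camera adjusted p = 0.0537 and 0.119), natural killer ligands without Adapalene replicate 3 (0.0552), epithelial markers without Adapalene replicate 3 or Combo replicate 2 (0.307 and 0.0600), and apoptosis regulators without Vehicle replicate 3 or Docetaxel replicate 3 (0.0829 and 0.0637). Gene calls for the interaction numbered 87 and 59 without Vehicle replicate 1 and 2, 94 and 115 without Docetaxel replicate 1 and 2, 88 and 387 without Adapalene replicate 1 and 2, and 128, 109 and 523 without Combo replicate 1, 2 and 3.

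**Figure D3:**
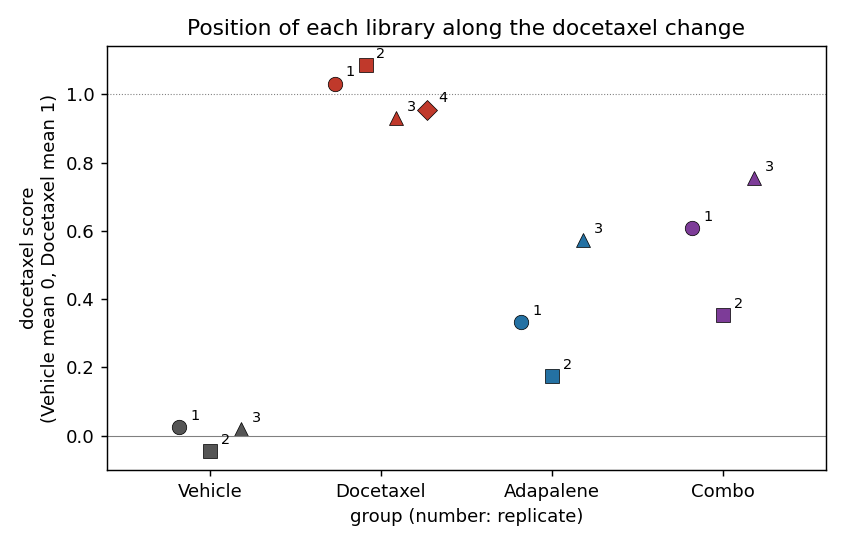
Docetaxel score of each library, from the 4082 genes called between Docetaxel and Vehicle, scaled so that the mean of Vehicle is 0 and that of Docetaxel is 1; numbers and symbols mark replicates. Adapalene libraries lie at 0.334, 0.175 and 0.573 and Combo libraries at 0.607, 0.353 and 0.754.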

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

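All tests of explanations here were chosen only after the results were seen, except those of the small structural RNAs, of the upper limits of the retinoid genes and of the residuals of all libraries regrouped.

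The test of the interaction flagged 227 genes, because the effect of adapalene differed with and without docetaxel. By camera at the preset correlation 10 lists differed as well, and 0 of them with an estimated correlation (lowest adjusted p = 0.0691), with medians of −1.003 for inflammatory genes, −0.26 for natural killer ligands, −0.99 for interferon-stimulated genes, 0.24 for mitosis, 0.31 for DNA replication, −0.20 for apoptosis regulators, 0.36 for cholesterol synthesis, 0.20 for epithelial markers, −0.36 for YAP and TGF-beta targets and −1.31 for replication histones. Single genes with such a difference were EGR1 (−4.14), IL24 (−3.35), IL6 (−2.48), IL1A (−1.85), RSAD2 (−1.82), SAMD9 (−1.52), H1-2 (−1.22), H2BC4 (−1.21), CDKN1A (−1.16), IFIT2 (−0.99), OASL (−0.97), PMAIP1 (−0.94), H2BC12 (−0.81), MCM6 (0.71), IGFBP5 (0.79) and NUP210 (0.90). The calls of IL1A and MCM6 were lost without Vehicle replicate 2 (edgeR adjusted p = 0.0597 and 0.0517), that of PMAIP1 without Vehicle replicate 1 or 2 (up to 0.0610), and that of IL6 in 10 of 13 fits without 1 library (up to 0.143).

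In 83 groups of 4 Docetaxel values, 2 held a library far from the other 3 by Dixon's test, where chance gives about 1 in 20. These were BMF in Docetaxel replicate 2 (7.96 CPM, others 6.05 to 6.33) and JUNB in Docetaxel replicate 3 (198 CPM, others 220 to 224). Some genes left unprinted after their values were seen held such a library too, so the share among printed genes is lower for that reason.

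Regroupings of libraries bear on how far the counts of calls exceed what the spread between technical replicates gives. The labelled split was the only 1 of 35 with as many calls for Docetaxel against Vehicle (highest other 155) and for Combo against Docetaxel (highest other 765). For both this argues against that spread as the source of the calls. For Adapalene and Combo against Vehicle it was 1 of 10 (highest other 0), too few splits to tell. For the interaction 6 of 100 regroupings gave as many calls, since whole drug effects enter some of them (up to 2696). After the effect of each drug was removed, 1 of 100 did, the labelled one (236 calls by limma, highest other 172), which argues against that spread here too. A difference between cultures that went with the groups would give the same results, so these regroupings cannot tell it from a drug effect.

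Between Adapalene and Combo 2 of 10 splits gave at least the 6 calls of the labelled split, and the other, Adapalene replicates 1 and 2 with Combo replicate 2 against the remaining 3, gave 1774. On the docetaxel score, the first measure tried, Adapalene replicate 3 (0.573) and Combo replicate 2 (0.353) lay as an exchange of their labels predicts, but histone transcripts, turned to only after that, lay the other way (log2 difference −0.50, summed CPM 170 and 241), which argues against an exchange. The share of mitochondrial counts stays open: its mean was 2.23% for Adapalene replicate 3 with Combo replicates 1 and 3 and 1.39% for the other 3, although the smallest of the former, 1.30%, lay below the largest of the latter, 1.66%. A deviation shared by libraries of the same replicate number stays open too, since the score was higher in Combo within each number (0.334 and 0.607, 0.175 and 0.353, 0.573 and 0.754), as was IL6 (16.7 and 41.6, 8.39 and 16.2, 30.7 and 66.0 CPM), and deviations correlated for numbers 2 and 3 (r of 0.529 and 0.415) but hardly for number 1 (0.0202). Variation between wells was not tested.

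The interaction that the design names compares the effect of adapalene with and without docetaxel. For histones that effect was not merely smaller with docetaxel. Of 37 tested core and linker histone genes 0 rose and 4 fell with adapalene alone (median log2 0.12). When it was added to docetaxel 0 rose and 26 fell (−1.16). Read the other way, the response to docetaxel was smaller with adapalene. If the 2 libraries lying near the other group were the whole cause, the calls left without them should be no more than chance gives, but 163 were left by limma, reached in 4 of 100 regroupings of residuals, the labelled one included (highest other 640), which argues against it, by a narrow margin. With the share of mitochondrial counts as a covariate there were 367, reached in 3 of 100 (highest other 1300), which argues in the same way against that share. If the Combo libraries held no docetaxel effect, histone transcripts should equal those of Adapalene, and their median was 0.79 higher, which argues against it. Carry-over of RNA without poly(A) tails could raise histone transcripts in Docetaxel libraries, and should then raise small structural RNAs alike. The median of 17 such RNAs was 0.46 (95% interval −0.09 to 1.11), below the lower quartile of the histones, 1.56. Of these RNAs 4 were called up and 0 down. Whether RNAs so small are carried over to the same degree as histone transcripts was not measured, so carry-over stays open.

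Retinoid target genes were not higher with adapalene as a list. If the spread between libraries hid a 2-fold rise, upper limits would reach beyond it, and for 20 of 24 members the upper 95% limit of the log2 change lay below 1, which argues against that. An exchange of the labels of the Adapalene and Docetaxel libraries stays open: the list should then rise in Docetaxel, where 4 of 24 members rose and 1 fell (median 0.12) and the list passed fry (adjusted p = 0.000558) but not camera (adjusted p = 0.273). Against Vehicle in Adapalene it passed neither (0.524 by fry). In Combo it passed camera against Adapalene (0.00735), a call lost with an estimated correlation, and not against Docetaxel (0.943). A response at earlier times than 48 h was not tested.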

How the results depend on the processing

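Fits without libraries over 2% mitochondrial counts, with that share as a covariate, without Adapalene replicate 3 and Combo replicate 2 together, and with a replicate block in only the 2 groups compared were chosen after seeing the data. No result passed its threshold in the other direction, but 4 list medians changed sign as their calls were lost: tubulin in Combo against Vehicle (−0.0019 without Vehicle replicate 3, up to 0.267 without another library), and in Combo against Adapalene YAP and TGF-beta targets (−0.0776 without Adapalene replicate 2, up to 0.353), hypoxia (−0.0393 without the 2 libraries) and metalloproteinases (−0.0081 without them). At a minimum of 2-fold (log2 1) calls were 914, 477, 813, 561 and 0 in the 5 comparisons (Docetaxel, Adapalene and Combo against Vehicle, Combo against Docetaxel, Combo against Adapalene) and 116 for the interaction, and calls shared in direction by Docetaxel and Adapalene were 162, against 973 without the minimum. Leaving out 1 library gave 2347 to 3760, 1494 to 2666, 2486 to 3971, 2292 to 3541 and 0 to 33 calls, and 59 to 523 for the interaction, with fewer libraries in each fit. Without a filter on low counts there were 128 calls between Combo and Adapalene and 946 for the interaction. Combo against Adapalene had 39 calls by DESeq2, 0 with only those groups, 379 without the 2 libraries and 27 with the covariate. The interaction had 485 by DESeq2 and 633 without libraries over 2%. The cause of these shifts was not tested. Lists past camera were 2, 1, 1, 2 and 2 of 22, and 0 for the interaction, with an estimated correlation, and fry passed 19 for Docetaxel against Vehicle and 4 for Combo against Adapalene. The correlations of drug effects were 0.51 (adapalene) and 0.61 (docetaxel) above 10 CPM, and 0.20 to 0.44 and 0.13 to 0.54 without 1 library. With the replicate number as a block, the 5 comparisons had 3792, 2829, 4033, 3558 and 2 calls and the interaction 199, and no call printed for Combo against Vehicle changed. With that block in only the 2 groups compared there were 5099 calls for Combo against Vehicle and 75 for Combo against Adapalene. Over all groups the 18 same-numbered pairs had a median r of −0.014, and 5 of 12 libraries, all of Adapalene or Combo, matched best with their own number. Under the naming rule the printed genes made 201 pairs of gene and comparison, some of which are not printed here. Of these pairs 153 were called and 48 were not. Leaving out 1 library lost a call in 45 fits and kept it in 1042, and it gained 6 and left 368 uncalled. The block lost 5 and gained 4, DESeq2 lost 0 and gained 2, and RLE scaling changed 0. Of 68 list calls the block and the CPM filter each lost 1, lysosome in Docetaxel against Vehicle (camera adjusted p = 0.0903 and 0.0668), the fit under 2% lost 11, that without the 2 libraries 9, fry 12, and the covariate 0.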

Other observations

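The families here were chosen after the data were seen, so their tests are not independent evidence. Immediate-early genes, which respond to signals within minutes, rose with docetaxel in 16 of 19 cases (median log2 1.5, adjusted p = 0.0143 with an estimated correlation), with adapalene in 12 with 1 falling (0.95, adjusted p = 0.339 with an estimated correlation) and with Combo in 16 with 1 falling (1.28, adjusted p = 0.117 with an estimated correlation). Among all 37 tested core and linker histone genes 34 rose with docetaxel (1.69, adjusted p = 0.0143 with an estimated correlation), and 26 fell from Docetaxel to Combo (−1.16, adjusted p = 0.114 with an estimated correlation). Proteasome subunit genes had 11 of 33 down with adapalene (−0.20, adjusted p = 0.527 with an estimated correlation) and 13 down with Combo (−0.18, adjusted p = 0.61 with an estimated correlation). Of 30 kinesins 14 fell and 3 rose with adapalene (adjusted p = 0.339 with an estimated correlation), and of 28 collagens 8 rose and 1 fell (adjusted p = 0.527 with an estimated correlation). Mitochondrially encoded genes had 0 of 18 called with either drug alone.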
